A study of Mus musculus with 3 samples.

How the data were processed

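RNA of primary mouse embryonic fibroblasts lacking Rb and Atm was measured on 3 Agilent 1-colour (Cy3) whole-genome expression arrays, with 1 array for each of 3 groups: cells given an empty vector, cells given a vector with a short hairpin RNA against Dnmt1, and cells given a vector for ATM. Groups were taken from the transfection label of each sample. With 1 array per group there was no replicate of a culture, so differences between arrays are given without a p-value and without a standard error, and the number of arrays limits the precision.

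The authors deposited scanner output made with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes and the file headers. The processed signal is an intensity on a linear scale from which local background and a spatial trend had been subtracted and in which spots near background carry a surrogate value, per the file headers; no scaling between arrays is recorded there. The series matrix that the authors deposited holds the same intensity values: each lay within 0.495% of the processed signal of the same spot, with column medians of 75.2, 80.4 and 68.6 for the empty-vector array, the Dnmt1 shRNA array and the array labelled ATM vector. Its scale is therefore linear and uncentred, and each column holds 1 array rather than a ratio. Other quantities from the deposited files, namely the flags for signal well above background, saturation and outlier spots, are per-spot marks of 0 or 1 set by the same software, per the file headers.

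Each array held 44397 spots, of which 43020 were not controls. Control spots were removed, as were 228, 235 and 167 outlier spots on the empty-vector array, the Dnmt1 shRNA array and the array labelled ATM vector. No spot was saturated. The log2 processed signal was averaged over the spots of a probe (39404 probes kept) and the 75th percentile of each array was subtracted. A probe counted in a comparison if it was well above background on at least 1 of the 2 arrays, and a gene's log2 ratio is the mean over its counted probes. Genes with at least 1 probe well above background on each array count as measured on both arrays. A gene with no probe well above background on 1 array has a bound: its brighter value was set against the higher of the lowest signal well above background on the dim array and the gene's own signal there, and such genes are given as at least N-fold different. Counts of genes at least 2-fold different use the measured log2 ratios. For the totals of each comparison, the counts that rest on bounds or on signals measured on both arrays are given beside them. Counts within gene lists are given with bounds only where stated. The others can include members with a dim signal whose bound is under 2-fold. Comparisons were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

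Probes were named through the RefSeq accession in the scanner files, without version numbers, and a table of RefSeq genes of the assembly GRCm38.p6. Of 39429 probes, 26406 matched 1 symbol, 0 matched several and 13023 matched none; the last keep the accession of the file. The array design was placed on mm9, a different build, so no coordinates are printed and the table was used for names, for the chromosome of a gene and for the order of genes along it. No probe sequences were available, so GC content was not checked, and signals of near-identical genes (Tuba3a and Tuba3b, members of the Rhox and Xlr families, the alpha-globin genes Hba-a1 and Hba-a2) may include cross-hybridisation.

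Before the data were examined, 28 gene lists were fixed, together with the alternatives and the rule for naming genes. The rule names Dnmt1, Atm and Rb1; per comparison with the empty-vector array the 10 genes with the highest and the 10 with the lowest log2 ratio that carry a symbol other than a provisional one, have every counted probe well above background on both arrays and have probes with one sign; the 3 genes with the largest bound in each direction; up to 4 members of each list with the largest absolute difference (bounds where 1 array is dim); and the 10 genes in each direction with the largest smaller difference in both comparisons. Of the genes that this rule names, 1 is left out. For each list the median log2 ratio of its tested members is given with its percentile among 10000 random lists of the same size matched on mean signal in 20 bins. That percentile describes these arrays and is not a p-value. A member dim on 1 array enters only through its signal on the other, so the percentile of a list with many such members can reflect that selection. Chromosome medians used genes measured on both arrays with a mean normalized log2 signal above -3, a limit chosen after the medians were seen.

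The slide and the scan were checked as batches. The empty-vector and Dnmt1 shRNA arrays were on slide 1 and scan 1, and the array labelled ATM vector was alone on slide 2 and scan 2, so no fit with the slide as a block could be made. The shared empty-vector array was examined by simulating 3 unchanged arrays in 20 draws with noise from the repeated spots. For that noise the outlier spots were kept, whereas the measured ratios leave them out, so the simulated noise may be too large. Alternatives were normexp background correction with an offset of 50 (limma 3.58.1, R 4.3.3; run on the median spot and background signals, since the deposited files hold no mean spot signal), median scaling, quantile normalization, cyclic loess, other filters on dim probes, the brightest probe per gene, the series matrix values, and thresholds of 1.5-fold and 3-fold. A common detection level for both arrays of a comparison and the subtraction of chromosome medians were added after the data were seen. The steps were tested on simulated data for the Dnmt1 shRNA comparison, with the same noise from repeated spots and 200 changed genes among 19359. Of the 100 changed by 1.5 on the log2 scale 96% passed 2-fold in the right direction, and of the 100 changed by 3, 100%. The changed genes were drawn only from genes with a probe well above background on all 3 arrays. Recovery of genes dim on 1 array was therefore not tested. Of 19159 unchanged genes 897 passed 2-fold through noise, 331 of them among the 17061 well above background on both arrays. Of unchanged simulated lists of 30 genes, 8.5% fell outside percentiles 2.5 to 97.5.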

Results

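Expression was profiled in primary mouse embryonic fibroblasts that lacked both Rb1, which encodes the retinoblastoma protein pRB, and Atm, a kinase of the DNA damage response. Cells were given an empty vector, a vector expressing a short hairpin RNA against Dnmt1, the maintenance DNA methyltransferase, or a vector for ATM. They were selected with puromycin at 4 ug/ml for 3 days, cultured for 4 more days and measured on 1 array per group. Probes well above background numbered 21706 of 39404 (55.1%) on the empty-vector array, 23476 (59.6%) on the Dnmt1 shRNA array and 21659 (55.0%) on the array labelled ATM vector. The lowest signal well above background was 37.8, 25.1 and 32.7 intensity units, respectively. Spots of one probe repeated on an array had a median SD of 0.046, 0.047 and 0.051 on the log2 scale. These spreads are technical, and no difference below has a replicate culture.

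The targeted genes were examined first. The single Dnmt1 probe had a processed signal of 4908 on the empty-vector array and 956 on the Dnmt1 shRNA array, a log2 ratio of -2.19 (4.58-fold lower, with 21.8% of the signal left). On the array labelled ATM vector it was 3169, a log2 ratio of -0.49. Of 2 Atm probes, 1 was not well above background on any array. The other had signals of 430, 366 and 409 on the empty-vector array, the Dnmt1 shRNA array and the array labelled ATM vector, so its log2 ratio in the array labelled ATM vector was 0.06, within the spread between probes. The position of the Atm probes relative to the deleted part or to the sequence in the vector was not known, so they check neither the knockout nor the vector, and the sample is called the array labelled ATM vector throughout. The Rb1 probe, for which the same holds, had log2 ratios of 0.70 in the Dnmt1 shRNA array and -0.10 in the array labelled ATM vector.

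**Figure D1:**
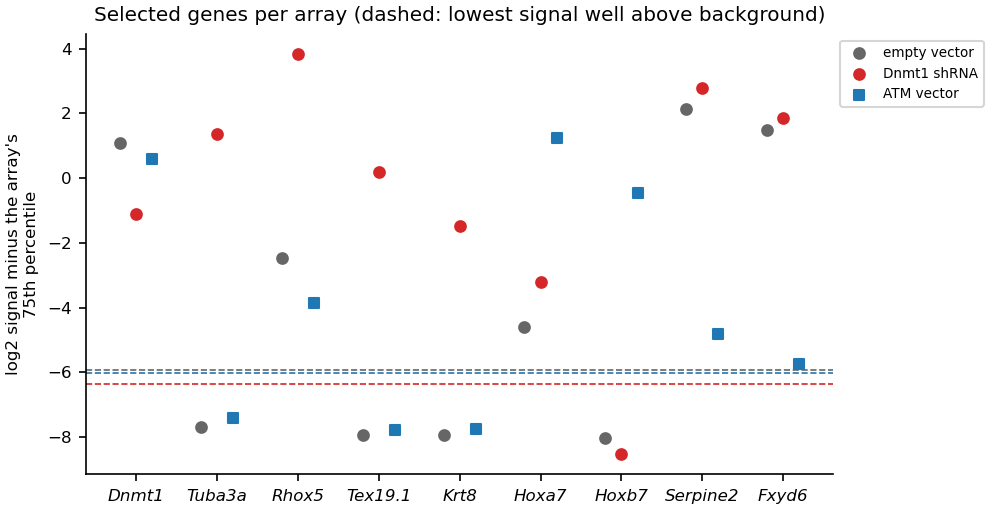
Log2 processed signal minus the 75th percentile of each array (y axis) for 9 genes (x axis) on the empty-vector array, the Dnmt1 shRNA array and the array labelled ATM vector, 1 point per array, with dashed lines at the lowest signal well above background of each array. Dnmt1 lay at -1.11 on the Dnmt1 shRNA array against 1.09 on the empty-vector array, Tuba3a, Tex19.1 and Krt8 were above the line on the Dnmt1 shRNA array alone, and Hoxb7 was above it on the array labelled ATM vector alone.

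The comparison of the Dnmt1 shRNA array with the empty-vector array asks which genes differ when Dnmt1 is depleted in these cells. With dim signals as measured, the germline list and the list of X-linked Rhox and Xlr genes had the highest medians of the 28 lists. Many of their members were below detection in the control. With bounds, the median of the epithelial markers (1.14) exceeded that of the germline genes (0.97). Of 29 tested members of the list of germline genes silenced by DNA methylation, 19 were at least 2-fold higher (14 with bounds) and 1 was at least 2-fold lower. Members well above background numbered 11 of 53 on the empty-vector array, 28 on the Dnmt1 shRNA array and 9 on the array labelled ATM vector. Tuba3a, a testis alpha-tubulin, was at least 159-fold higher, Tuba3b was 113-fold higher, Tex19.1, a germ-cell gene that restrains transposons, was at least 70.1-fold higher and Tex101, a germ-cell surface protein, was at least 43.4-fold higher. The median log2 ratio of the list was 2.93, or 0.97 with dim members at their bound, and lay at percentile 100 of random lists. Of 11 tested Rhox and Xlr genes, 8 were at least 2-fold higher and 0 lower, with a median of 4.63, or 2.47 with bounds (percentile 100). Rhox5, a reproductive homeobox gene, was 79.9-fold higher, and Xlr, Xlr3b and Xlr4b were at least 16.5-fold, 14.1-fold and 10.3-fold higher. Because many of these genes were dim on the empty-vector array, their sizes depend on the background and on the members counted. The 2 percentiles likewise rest on members selected partly by their signal on the Dnmt1 shRNA array. The germline median was 0.94 with normexp, 0.30 over members well above background on all 3 arrays and 0.46 without a filter, and that of the Rhox and Xlr genes was 1.99, 2.94 and 0.98.

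Markers of cell types, fibroblasts included, also differed. Of 17 tested epithelial markers, 9 were at least 2-fold higher and 0 lower, with a median log2 ratio of 1.14 (percentile 100; 0.55 over markers well above background on all 3 arrays, and 0.06 without a filter). On the empty-vector array 10 of 26 markers were well above background, so the other tested markers entered through their signal on the Dnmt1 shRNA array. The keratins Krt18 and Krt8, intermediate filament proteins of simple epithelia, were at least 39.8-fold and 22.0-fold higher, the desmosome protein Dsp was at least 4.61-fold higher and Krt14 was 4.24-fold higher. Fibroblast matrix genes had a median of 0.25 (percentile 100), with 12 of 54 at least 2-fold higher and 1 lower. They included the surface protein Thy1 at least 36.2-fold, the matrix protein Dpt at least 12.3-fold, Fmod 5.07-fold and Postn 3.27-fold higher. Of 30 contractile smooth muscle genes 5 were higher (3 with bounds) and 0 lower, with a median of 0.25 (percentile 100; lowest 0.13 under the alternatives). Among them were Rgs5, at least 7.82-fold higher, and Actg2, a smooth muscle actin, 7.01-fold higher.

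Growth-related lists shifted by smaller amounts. None of the 58 E2F-regulated S-phase genes was 2-fold different, yet the median log2 ratio was -0.28 (percentile 0.00), with Orc1 at -0.68, Mcm10 at -0.60, Mcm5 at -0.57 and Cdc45 at -0.46. The 51 mitotic genes had a median of -0.24 (percentile 0.00; 0 higher, 0 lower), and Cdc25b, Bub1 and Kif18a stood at -0.74, -0.53 and -0.50. The median of 37 sterol synthesis genes was -0.28 (percentile 0.00; 0 higher, 0 lower), with Pmvk at -0.88, Lss at -0.73 and Fasn at -0.70. Of 41 p53 target genes 5 were at least 2-fold higher and 1 lower, with a median of 0.30 (percentile 100). Gdf15, a stress-induced cytokine, was 12.4-fold higher, Cdkn1a, an inhibitor of cyclin-dependent kinases, 2.44-fold, Cd80 2.14-fold and Fas, a death receptor, 2.06-fold, whereas Plk3 was 2.05-fold lower. The 2 probes of Cdkn1a gave log2 ratios of 0.71 and 1.87. Secretory genes linked to senescence had a median of 0.14 (percentile 99.9; 0.06 over members well above background on all 3 arrays, and 0.04 without a filter), with 7 of 39 higher and 3 lower; Cxcl5, a chemokine, was 15.9-fold, Igfbp6 10.4-fold and Mmp3 5.98-fold higher. Of 47 interferon-stimulated genes 5 were higher and 2 lower, with a median of 0.25 (percentile 100); Oasl1 was at least 6.01-fold and Ifitm1 2.95-fold higher, and the chemokine Cxcl10 was 2.78-fold lower.

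Imprinted genes in the Dnmt1 shRNA array had a median of 0.23 (percentile 99.8; 4 of 40 higher, 0 lower; 0.09 over members well above background on all 3 arrays), led by Ddc at least 4.80-fold and Peg12 2.20-fold higher. Cell cycle inhibitors and tumour suppressors had a median of 0.17 (percentile 99.98; 5 of 51 higher, 0 lower). Medians below 0 were found for DNA damage response and repair genes (-0.19, percentile 0.01, 0 of 48 different by 2-fold), immediate early genes (-0.26, percentile 0.02, 0 higher and 2 lower of 32, Nr4a1 3.27-fold and Nr4a2 2.12-fold) and clustered protocadherins (-0.24, percentile 0.17, 0 of 15). Stress genes of the unfolded protein and amino acid responses had a median of 0.05 (percentile 99.2, 0 of 35). Lists within the middle 95% of random lists were the DNA methylation machinery (-0.12, with Dnmt1 the 1 member of 27 at least 2-fold lower and Tet2 at 0.63), pluripotency genes (-0.02; 2 of 16 higher), oxidative stress genes (-0.06; 5 of 39 higher, with Gpx3 10.96-fold and Gsta3 3.23-fold), homeobox cluster genes (-0.11; 1 of 10 higher), sex chromosome genes (-0.14; 1 of 4 higher; -3.30 with chromosome medians subtracted, an alternative added after the data were seen, in which few genes give the Y median) and housekeeping genes (-0.03, 0 of 24 different by 2-fold, but 0.04 after quantile normalization and 0.07 after cyclic loess). Also within that range were striated muscle markers (0.67; 6 of 15 higher and 1 lower, or 1 and 1 with bounds), fat, cartilage and bone markers (0.30; 5 of 19 higher and 1 lower), endothelial markers (0.53; 2 of 11 higher), blood and macrophage markers (0.51; 3 of 11 higher) and neural markers (0.18; 2 of 15 higher). Without a filter the medians of the last 3 lists were -0.17, -0.08 and -0.20, the endothelial median was 0.13 with normexp and the neural median was -0.02 after quantile normalization. The medians of pluripotency and oxidative stress genes also changed sign under some alternatives, so these lists have no clear direction.

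In all, 1486 of 19359 genes were at least 2-fold higher in the Dnmt1 shRNA array and 432 were at least 2-fold lower. Among genes well above background on both arrays the numbers were 585 and 171, and by bounds a further 343 and 180 passed 2-fold. In the simulation with noise from repeated spots, 897 of 19159 unchanged genes passed 2-fold, 331 of them well above background on both arrays. Those numbers hold both directions together, so the numbers of genes lower may be no larger than noise gives. The simulated noise kept outlier spots, which the measured ratios leave out. It may therefore be too large, and the simulation cannot decide this. Besides the genes above, the highest ratios on signals measured on both arrays belonged to Mc3r, a melanocortin receptor, at 107.2-fold, Ica1l at 49.5-fold, Gtsf1, a gametocyte gene of the piRNA pathway, at 48.5-fold, Chil3 at 45.0-fold, Olfr1466 at 26.2-fold, Serpinb6b at 25.7-fold, Ahsg at 23.5-fold and Sncg at 22.5-fold. Rhox2c was at least 76.8-fold higher. The lowest were Tspan11 at 9.14-fold, Tnfsf11, the cytokine RANKL, at 7.26-fold, Spink2 at 6.88-fold, Syt3 at 5.51-fold, Slc5a9 at 5.15-fold, Arhgef26 at 4.85-fold, Dnmt1 itself, Vax2os at 4.404-fold, Epgn at 4.11-fold and Popdc2 at 4.01-fold lower. By bounds Pygl, liver glycogen phosphorylase, was at least 18.7-fold, Igll1 at least 17.0-fold and Ifna11 at least 13.3-fold lower. Different probes of one gene differed with a pooled SD of 0.21 on the log2 scale. Both arrays were on slide 1, so this comparison lies within 1 slide and scan. With the common detection level, added after the data were seen, 893 genes were higher and 269 lower.

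**Figure D2:**
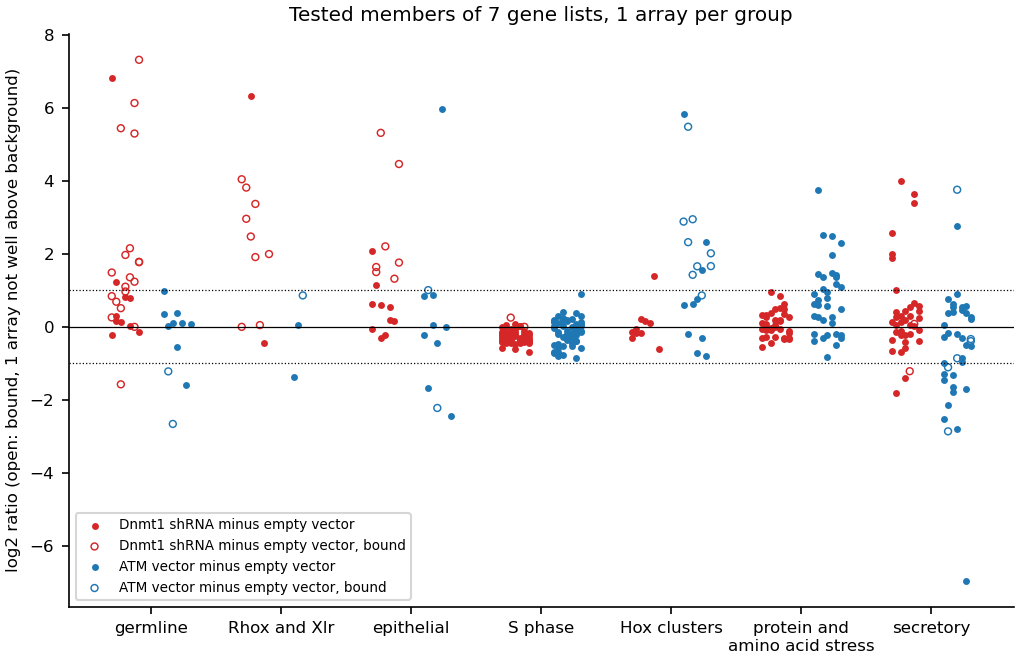
Log2 ratio (y axis) of each tested member of 7 gene lists (x axis) in the Dnmt1 shRNA array and in the array labelled ATM vector, both against the empty-vector array; open points are bounds for genes not well above background on 1 array, and dotted lines mark 2-fold. Germline and Rhox and Xlr genes extended upward in the Dnmt1 shRNA array, with 14 of 29 and 8 of 11 at least 2-fold higher with bounds, and Hox cluster genes in the array labelled ATM vector, with 11 of 19.

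The comparison of the array labelled ATM vector with the empty-vector array asks which genes differ between cells given a vector for ATM and cells given an empty one, per the labels. The homeobox cluster genes, which encode positional identity along the body axis, were among the most strongly higher: of 19 tested, 12 were at least 2-fold higher and 0 lower, with a median log2 ratio of 2.57, or 1.54 with bounds (percentile 100). Members well above background numbered 10 of 39 on the empty-vector and on the Dnmt1 shRNA array and 19 on the array labelled ATM vector. Hoxa7 was 57.1-fold higher, and Hoxb7, Hoxb13 and Hoxb6 were at least 44.7-fold, 7.71-fold and 7.38-fold higher. Over members well above background on all 3 arrays the median was 0.61, and without a filter it was 0.14. Of the 19 tested, 10 were measured on both arrays and the others entered through the array labelled ATM vector, so the percentile partly rests on that selection. Stress genes of the unfolded protein and amino acid responses had a median of 0.62 (percentile 100), with 13 of 35 at least 2-fold higher and 0 lower. Cth, an enzyme of cysteine synthesis, was 13.6-fold higher, and Ddit3 and Trib3, both induced by integrated stress signalling, and Chac1, a glutathione-degrading enzyme, were 5.74-fold, 5.62-fold and 4.91-fold higher.

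Many secretory genes and some matrix genes were lower in the array labelled ATM vector. Of 39 senescence-associated secretory genes 15 were at least 2-fold lower (12 with bounds) and 2 higher, with a median of -0.50, or -0.33 with bounds (percentile 0.00). The median was -0.27 over members well above background on all 3 arrays and -0.14 without a filter. Serpine2, a protease inhibitor, was 124-fold lower, Igfbp3 at least 7.27-fold and the chemokine Ccl5 7.02-fold lower, whereas Serpinb2 was at least 13.5-fold higher. Among fibroblast matrix genes 12 of 52 were lower and 4 higher (median -0.09, percentile 2.49). The fibrillin Fbn2 stood at -6.57 on the log2 scale by its probe well above background on both arrays, and its other probe was not above background on this array. Fap was at least 23.8-fold, Col14a1 13.6-fold and Lum 9.23-fold lower, and Postn was higher by 2.91 on the log2 scale; the 2 Col14a1 probes gave -6.24 and -1.29. Cell cycle inhibitors and tumour suppressors had 9 of 49 lower and 2 higher (median -0.21, percentile 0.35): the Wnt antagonist Sfrp1 was 44.9-fold and Dapk1, a death-associated kinase, at least 15.3-fold lower, and Runx3 was 3.44-fold higher. Of 44 interferon-stimulated genes 15 were lower and 3 higher (median -0.17, percentile 3.56, within the middle 95%, and 0.13 over members well above background on all 3 arrays), with Trim25 8.38-fold lower and Ifitm1 31.2-fold and Ifi27l2a 7.05-fold higher. The median of 41 p53 target genes was -0.23 (percentile 0.13; 4 higher, 3 lower); the growth arrest gene Gadd45a was 8.04-fold and Perp 4.28-fold higher, and Pmaip1 was 2.57-fold lower.

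Lineage and imprinted genes differed in both directions. Striated muscle markers had a median of 0.95 (percentile 99.6; 5 of 12 higher, 1 lower), or 0.53 with normexp and 0.21 without a filter, with the troponin Tnni2 7.94-fold, Tnnt3 at least 4.02-fold and Tnnt2 3.26-fold higher. Of 29 contractile smooth muscle genes 10 were higher and 2 lower (median 0.17, percentile 82.3, but -0.02 after quantile normalization and -0.01 over members well above background on all 3 arrays), with Actg2 25.3-fold, Des at least 6.95-fold and Itga7 6.77-fold higher. Among 11 epithelial markers 2 were higher and 3 lower (median -0.01, percentile 41.6): the basal keratin Krt14 was 63.1-fold higher, and Krt19 was 5.41-fold lower. Of 38 imprinted genes 8 were higher and 5 lower (median 0.09, percentile 71.3; from 0.05 to 0.31 under the alternatives). Mest stood at 3.01 and 3.42 on the log2 scale by its 2 probes well above background on both arrays and Asb4 at 4.10 by its 1 such probe, and Zrsr1 was at least 44.7-fold and Dlk1 at least 14.2-fold lower. Clustered protocadherins had a median of -0.69 (percentile 0.05; 5 of 19 higher, 6 lower), with Pcdhb1 at least 6.28-fold higher and Pcdhga1, Pcdhb18 and Pcdhb17 3.61-fold, 3.34-fold and 3.19-fold lower; after the median of each chromosome was subtracted, an alternative added after the data were seen, the median of the list was -0.32. It was -0.31 with normexp, -0.18 without a filter and -1.07 over members well above background on all 3 arrays. Oxidative stress genes included the glutathione transferases Gsta2, Gsta1 and Gsta4 at 6.92-fold, 6.36-fold and 5.98-fold higher and Gpx3 at least 5.98-fold lower (median 0.07, percentile 52.3; 5 of 39 higher, 3 lower). Of blood and macrophage markers, the embryonic globin Hbb-bh1 and the alpha-globin Hba-a1 were at least 59.7-fold and 58.8-fold higher, while the list median was 0.03 (percentile 49.5; 4 of 12 higher, 2 lower).

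S-phase genes in the array labelled ATM vector had a median of -0.15 (percentile 0.58, 0 of 56 different by 2-fold) and mitotic genes -0.14 (percentile 1.07, 0 higher and 1 lower of 51, Foxm1 at 2.45-fold). The 3 tested sex chromosome genes, all Y-linked, were lower by less than 2-fold, at -0.94 for Ddx3y, -0.87 for Eif2s3y and -0.59 for Uty (median -0.87, percentile 2.12; -0.10 for the whole list without a filter). Housekeeping genes had a median of 0.35 (percentile 98.6, 0 of 24), and 0.07 after quantile normalization. The germline list, with 11 members tested, had 0 higher and 3 lower (median 0.09, percentile 57.3), and Tex15 was at least 6.32-fold lower. For 3 Rhox and Xlr genes the median was 0.05 (percentile 53.4; 1 higher, 1 lower). Lists within the middle 95% of random lists also comprised the DNA methylation machinery (-0.01, 0 of 26 different by 2-fold, with Cdca7 at -0.83 and Dnmt3a at -0.79), pluripotency genes (0.20; 4 of 15 higher, 1 lower), repair genes (-0.13; 1 of 47 lower), sterol synthesis genes (-0.03; 1 of 37 higher), immediate early genes (-0.09; 4 of 32 higher, 7 lower), fat, cartilage and bone markers (0.09; 3 of 16 higher, 6 lower), endothelial markers (-0.03; 1 of 8 lower) and neural markers (0.22; 4 of 14 higher). Under some alternatives the medians of the sterol synthesis, immediate early, oxidative stress, germline, and Rhox and Xlr genes and of the endothelial, epithelial, blood and macrophage, and fat, cartilage and bone markers changed sign in this array.

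In all, 1561 of 18463 genes were at least 2-fold higher and 1469 at least 2-fold lower in the array labelled ATM vector, of which 947 and 728 were measured on both arrays, and by bounds a further 337 and 446 passed 2-fold. The highest ratios on both arrays were those of Cox6a2, a muscle subunit of cytochrome oxidase, at 64.2-fold, Krt14, Lypd2 at 59.1-fold, Hoxa7, the alpha-globin Hba-a2 at 50.5-fold, Slurp1 at 39.9-fold, Ifitm1, Pi16 at 30.9-fold, Naip2 at 29.1-fold and the integrin Itgb7 at 28.8-fold. Tlx2, a homeobox gene, was at least 156-fold higher. Among the lowest were Fxyd6 at 149.9-fold, Slc43a3 at 139.9-fold, Serpine2, the membrane linker Ezr at 98.1-fold, Prl2c1 at 76.3-fold, Svep1 at 72.0-fold, Npr3 at 63.7-fold, Epyc at 53.1-fold and the cytokine Il33 at 46.8-fold lower. Emb, Rspo3 and Plxdc2 were at least 735-fold, 498-fold and 327-fold lower.

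Several measures set this array apart. It was alone on slide 2 and scan 2, so slide, scan and vector cannot be told apart. The 5 of 10 spike-in controls measured on all arrays differed from the empty-vector array by a median of -2.21 on the log2 scale after scaling, against 0.11 for the Dnmt1 shRNA array, and the extraction software marked this array for evaluation. Probes of one gene differed with a pooled SD of 0.33, against 0.21 in the other comparison, and the 7 Gapdh probes ranged from -0.88 to 0.32, against -0.44 to -0.15. The log2 ratios of all genes measured on both arrays were more spread too, with an SD of 0.75 against 0.50. The larger spread between probes need not be technical. Chromosome medians also differed: over 9637 autosomal genes, the median log2 ratio of chromosome 10 was 0.44 above that of all genes (95% bootstrap interval over genes, 0.41 to 0.49), that of chromosome 18 was at -0.38 and that of chromosome 2 at -0.29, over genes above a signal limit that was chosen after these medians were seen. The SD of the 19 autosomal medians was 0.19, against 0.03 in the Dnmt1 shRNA array, where the largest absolute value was 0.06.

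**Figure D3:**
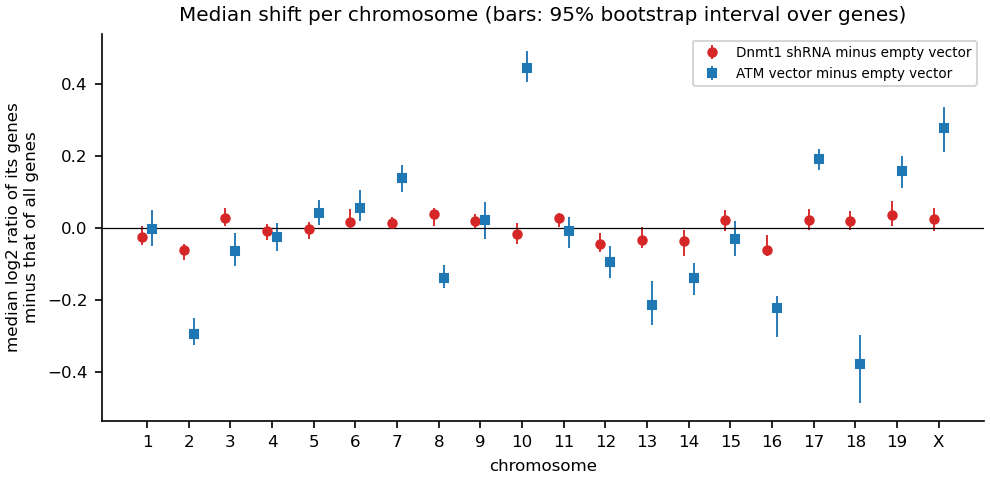
Median log2 ratio of the genes of each chromosome minus that of all genes (y axis) for chromosomes 1 to 19 and X (x axis), in the Dnmt1 shRNA array and the array labelled ATM vector against the empty-vector array; bars are 95% bootstrap intervals over genes, which are not independent replicates. The array labelled ATM vector ranged from -0.38 on chromosome 18 to 0.44 on chromosome 10, and the autosomes of the Dnmt1 shRNA array lay within 0.06 of 0.

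Both comparisons used the same empty-vector array, and their overlap asks which genes differ alike after either vector. Genes higher in both included Cox6a2 (11.1-fold in the Dnmt1 shRNA array and 64.2-fold in the array labelled ATM vector), Actg2 (7.01-fold and 25.3-fold), Sncg (22.5-fold and 6.89-fold), the thromboxane receptor Tbxa2r (11.2-fold and 5.53-fold), Slc11a1 (5.45-fold and 5.41-fold) and S100b (6.96-fold and 5.25-fold), followed by Dmpk, Plin4, Fam180a and Naip2. Lower in both were Spink2 (6.88-fold and 6.55-fold), the growth factors Epgn (4.11-fold and 3.77-fold) and Ereg (2.65-fold and 3.44-fold), Cxcl10 (2.78-fold and 6.62-fold), Apom (3.45-fold and 4.18-fold) and Galm (3.12-fold and 4.14-fold), followed by Zbtb49, Caly, Doc2a and Ptpn5. Of 18033 genes tested in both comparisons, 298 were at least 2-fold higher in both, where independent lists would share 50.6, and 329 were lower in both, where independent lists would share 35.2. Simulated unchanged arrays against 1 control shared a mean of 94.8 and 94.5 genes (at most 118 in either direction). A gene dim on the empty-vector array was tested in both comparisons only if it was well above background on both other arrays. So 765 of the 1486 genes higher in the Dnmt1 shRNA array remained, against all 432 lower. That selection can itself raise the overlap. The simulation kept the detection flags of the real arrays, so neither reference number accounts for it. In opposite directions, 152 genes were higher in the Dnmt1 shRNA array and lower in the array labelled ATM vector (62.3 for independent lists), and 11 the reverse (28.6).

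Restricted to 16583 genes measured on all 3 arrays, 146 genes were higher in both (27.0 for independent lists, 32.6 in the simulation) and 46 lower in both (5.22 and 34.8). The highest simulated values were 39 and 51, so the number lower in both lay within that range. Since the simulated noise kept outlier spots and may be too large, this does not show that noise accounts for that number. Across genes, which are not independent replicates, the log2 ratios had a Pearson r of 0.31 and a Spearman rho of 0.16, with a covariance of 0.22 against a simulated 0.052 (simulated r 0.49). Over genes measured on all arrays r was 0.12, and the covariance was 0.043 against a simulated 0.026. That simulation holds only the noise between repeated spots of an array. With the whole spread of the Dnmt1 shRNA comparison taken as error instead, the simulated covariance was 0.090, which is below the 0.22 observed over all genes and above the 0.043 observed over genes measured on all arrays. Under that error at most 36 genes were higher in both and 40 lower in both over all genes. Over genes measured on all arrays the maxima were 35 and 39, and each observed number lay above its maximum. However, that error was 1 SD of 0.318 for every probe, bright or dim, taken from probes well above background on all 3 arrays. It gave fewer shared genes than the noise of repeated spots, which varies with signal. Lying above it therefore does not show that the 46 genes lower in both exceed error. Part of the covariance may come from the empty-vector array that both comparisons share.

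**Figure D4:**
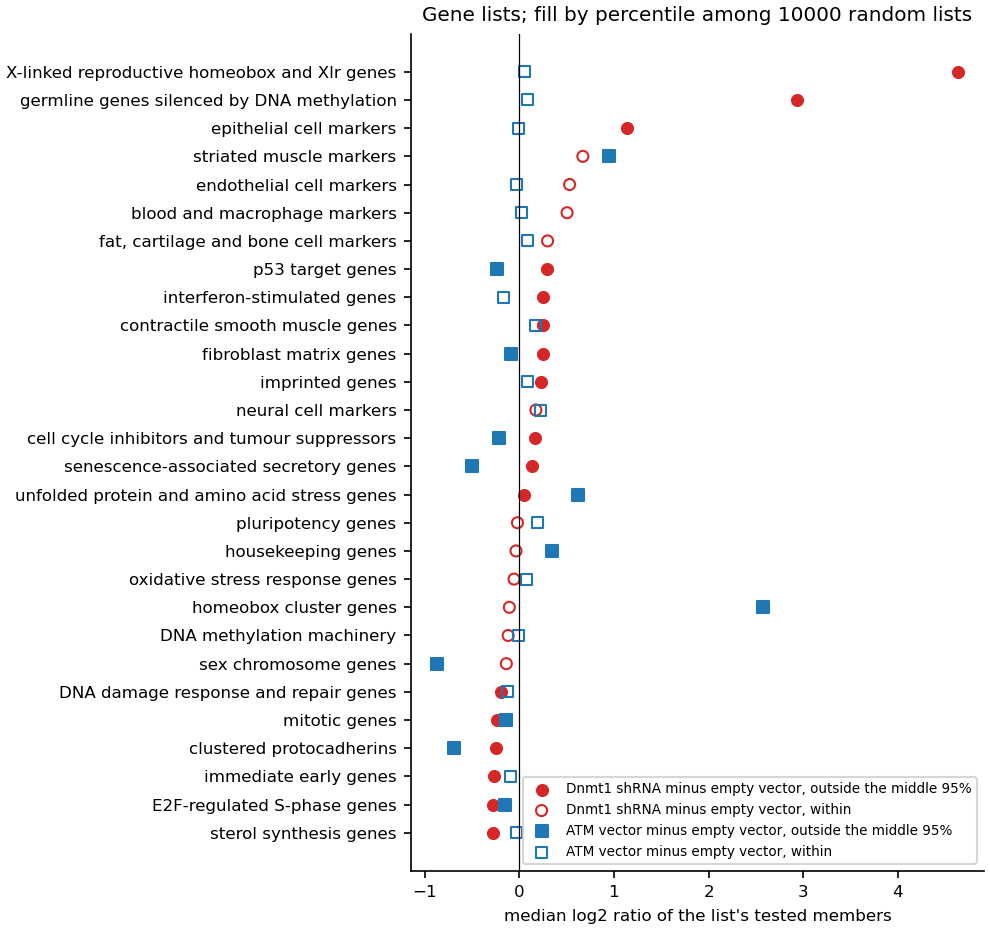
Median log2 ratio (x axis) of the tested members of each of the 28 gene lists (y axis) in the Dnmt1 shRNA array (circles) and the array labelled ATM vector (squares) against the empty-vector array, with dim signals as measured; filled points lie outside the middle 95% of 10000 random lists matched on signal. Rhox and Xlr genes at 4.63 and germline genes at 2.93 stand furthest right for the Dnmt1 shRNA array, and homeobox cluster genes at 2.57 for the array labelled ATM vector.

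Set directly against each other, 1539 of 19525 genes were at least 2-fold higher in the array labelled ATM vector than in the Dnmt1 shRNA array and 2436 were lower, again across slides. Among genes measured on both arrays the numbers were 1121 and 1143, and by bounds a further 315 and 673 passed 2-fold. The germline genes were lower there, with 23 of 28 at least 2-fold lower (18 with bounds) and 0 higher (median -2.95, or -1.32 with bounds, percentile 0.00), as were 8 of 11 Rhox and Xlr genes (median -4.32, or -2.55 with bounds). Of the 28 germline genes 9 were measured on both arrays, so the percentile partly rests on members selected by their signal on the Dnmt1 shRNA array. Against the empty-vector array the germline median of the array labelled ATM vector was 0.09 over 11 tested members. Homeobox cluster genes were higher, with 12 of 19 at least 2-fold higher and 0 lower (median 2.07, or 1.85 with bounds, percentile 100). Of these 19, 10 were measured on both arrays, so this percentile also partly rests on members selected by their signal on 1 array.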

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

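The common detection level and the subtraction of chromosome medians were chosen after the data were seen; the other alternatives were fixed before the data were examined. No paired analysis was possible because each group had 1 array, and no array could be left out; the slide as a block was not run for the same reason. The log2 ratios of Dnmt1, Atm and Rb1 moved by less than the spread between probes in 60 of 60 alternative values. Each of these genes has 1 counted probe, so the filter on all 3 arrays, the brightest probe and the common detection level could not move them. Of the 56 list medians, the 29 outside the middle 95% of random lists changed sign 0 times and the others 32 times. Of 2011 alternative values of named genes at least 2-fold different 62 were under 2-fold, 38 of them with normexp, and 0 had the opposite sign. These genes were named for large differences on the same arrays, which makes a change of sign unlikely. Where such a gene has 1 probe, the brightest-probe setting cannot move it. The counts of genes higher and lower in the Dnmt1 shRNA array, higher and lower in the array labelled ATM vector, and higher and lower in both are given in that order. With normexp, whose offset shrinks dim signals by construction, they were 582, 102, 890, 792, 86 and 63. With probes well above background on all 3 arrays, where fewer genes are tested, they were 460, 109, 921, 702, 143 and 38. At 1.5-fold they were 2534, 918, 3172, 2656, 623 and 496, by construction. At 3-fold the first 5 were 908, 265, 876, 939 and 129. Without a filter, where more dim genes are tested, 1139 genes were lower in the Dnmt1 shRNA array, 514 higher in both and 684 lower in both. At the common detection level 893 were higher and 269 lower in the Dnmt1 shRNA array, 181 higher in both and 198 lower in both, since dim differences shrink by construction. The correlation of the log2 ratios across genes was 0.13 with normexp, 0.11 with probes well above background on all arrays, 0.25 without a filter, 0.15 at the common detection level and 0.045 over the brighter genes. Medians, quantiles, cyclic loess, the brightest probe, the series matrix values and chromosome medians left each of these counts within 1.5 times its value; the series matrix holds the same signals rounded, so its agreement says nothing about stability. Signal over background limits the dim genes: 897 of 19159 unchanged genes passed 2-fold in the simulation of the Dnmt1 shRNA comparison, with noise that kept outlier spots.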

Other observations

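The tests of the lower background, of germline silencing, of parts of chromosomes and of admixed cells were chosen after the results they concern were seen. Those of scaling, whole chromosomes, signal intensity, gene density and probe-split covariance were written before they were run. However, the scaling test uses the common detection level, which was added after the data were seen. The tests of whole chromosomes, signal intensity and gene density use chromosomes picked from the medians they concern. Along the chromosomes, the array labelled ATM vector differed in long stretches. In 4 equal stretches in gene order, chromosome 10 had median shifts of 0.26, 0.52, 0.44 and 0.50 on the log2 scale, chromosome 18 of 0.06, -0.57, -0.53 and -0.49, and chromosome 6 of 0.21, 0.30, 0.05 and -0.57. Chromosomes 10, 18 and 2 were picked out after the chromosome medians were seen. The X chromosome had a median shift of 0.28 over 300 genes, and the 2 Y-linked genes above the signal limit had one of -0.92. In the Dnmt1 shRNA array the X chromosome stood at 0.03.

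More genes were higher than lower in the Dnmt1 shRNA array, and a lower background on that array does not account for it alone, since the number higher was 3.32 times the number lower once both arrays were raised to a common detection level. Scaling does not account for it either: the lowest such ratio over quantile, cyclic loess, normexp and median scaling was 2.09. A candidate biological explanation for part of the excess is the loss of silencing after Dnmt1 depletion: of 42 listed germline genes not above background on the empty-vector array 12 were at least 2-fold higher at the common level, against a mean of 1.19 and at most 6 in 10000 random lists of such genes matched on the empty-vector signal (percentile 100). This test replaced a count of silent germline genes that became detected (18 of 42, against 14.3% of all silent named genes) and a median over members chosen partly for their signal on the Dnmt1 shRNA array. The 12 genes are few beside the 893 genes higher there, so the rest of the excess stays open, and without a second hairpin or a replicate culture an effect of this 1 culture remains possible.

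For the shifts along chromosomes and the large losses of the array labelled ATM vector, a trend with signal intensity is argued against by chromosome 10, whose shift was 0.43 after cyclic loess, and a trend with local gene density by its shift of 0.42 after that trend was removed. A minority of other cells added to this sample would lower no gene by more than 2-fold, yet 47 genes with 2 or more probes had each probe at least 4-fold lower (28 with dim probes at their bound, and 12 with every probe well above background on both arrays, fewer than the test asked for), against 0 in the Dnmt1 shRNA array. This test replaced a count of strongly lower genes that included bounds. It does not address other cells present in the empty-vector culture and absent from this one. Copies of whole chromosomes alone are also argued against, since the first stretch of chromosome 18 was shifted against its chromosome (-0.061 in the chromosome's own direction). Gains and losses of parts of chromosomes stay open: genes 25 places apart had a rank correlation of 0.19 (0.08 after chromosome medians were subtracted), but this test was added once that of whole chromosomes had failed and the stretches had been seen, and any regional effect would give it. Slide, labelling, probe GC content, the state or origin of this 1 culture and ATM itself also stay open. With 1 array of 1 culture on its own slide, slide, culture and vector cannot be told apart.

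Genes that differ the same way in both comparisons could reflect spot error of the shared empty-vector array. When the 2 comparisons were taken from different probes of a gene, the covariance was 81.6% of that from the same probe over 3346 genes (95% bootstrap interval 54.4% to 104%). Spot error as the main source would give under 50%, and the bound set against it was 80%, which lies inside the interval. Genes with several probes are also a small part of the 18033 genes tested in both comparisons, which keeps spot error open for the others. A state of the single empty-vector culture would be carried by every probe of a gene and cannot be told apart from a shared effect of both vectors.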
